A study of Mus musculus with 41 samples.

How the data were processed

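RNA from mouse epidermal stem cells was measured on 41 arrays, 20 from mice on a control diet and 21 from mice on a high fat diet. The cells came from wild type female C57B6/J mice that were 15 weeks old and had been on their diet for 7 weeks, starting at 8 weeks of age. Collection was at 6 zeitgeber times, ZT0, ZT4, ZT8, ZT12, ZT16 and ZT20, which are 4 h apart. The design text plans 4 mice per diet and time point, or 48 in all, and the 41 arrays analysed here make groups of 2 to 4. The arrays carry numbered replicates, and the labels do not say of each array that it is a separate mouse, so the p-values measure the spread between arrays. The design text assigns the mice killed on 1 day to 1 time point. It does not settle whether the mice of both diets were killed on the same day, so collection day cannot be told apart from time point and may differ between the diets within a time point.

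Per the labels' protocols, 25 ng of total RNA was amplified by WTA2 for 17 cycles, and 8 µg of cDNA was fragmented and labelled with biotin. Values were made with RMA by the authors, per the submitters' processing notes, and are on the log2 scale. RMA corrects background, normalizes between arrays and summarises the probes of a probe set. Its version, and whether a batch adjustment followed, are not given in the sources used here. The log2 scale of the deposited values rests on their range of 2.17 to 13.5. Array medians lay between 6.41 and 6.44, no pair of arrays was identical, and correlations between arrays ran from 0.953 to 0.996. Scanner files were not used here, so the signal over background of each probe set is unknown, and the number of arrays limits the precision.

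The table holds 45141 probe sets, of which 104 are control probe sets. The platform annotation gave 1 gene for 28898 probe sets and several genes for 551, which were left out. The remaining 15692, control probe sets included, are unnamed here. Symbols were updated through Entrez identifiers, and 17055 of 17097 gene symbols are in the reference gene table. For the 7180 genes with more than 1 probe set, the probe set with the highest mean over all arrays stood for the gene. The platform annotation can be old, and no coordinates are given because no genome build is named with the table.

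All tests used limma 3.58.1 in R 4.3.3, with data.table (version 1.17.8) for reading, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Diet was tested in a model with a mean for each of the 12 groups, fitted to all arrays with lmFit and eBayes (29 residual and 2.63 prior degrees of freedom). Contrasts were high fat minus control at each time point and their equally weighted mean, called the diet average. An F test of 5 coefficients asked whether the diet effect differed between time points. Rhythms were fitted as a 24 h cosine with its own mean, amplitude and peak in each diet (35 residual degrees of freedom), with a test of each diet and of the difference between diets. Amplitude is the distance from the mean to the peak on the log2 scale. Adjusted p means Benjamini-Hochberg over all 17097 genes, with a threshold of 0.05. No filter on low values was applied. Peak times carry no more resolution than the 4 h sampling allows.

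The 31 gene lists held 424 members, of which 377 were measured. They cover the circadian clock, basal, bulge and suprabasal keratinocytes, stress keratins, S phase, mitosis, fatty acid oxidation, fatty acid synthesis, cholesterol synthesis, oxidative phosphorylation, glycolysis, antioxidant, p53, NF-kB, interferon, unfolded protein, heat shock, immediate early, glucocorticoid, BMP and Wnt genes, and markers of 9 other cell types or structures. Shifts of a list by diet were tested with camera, with its preset correlation of 0.01 and again with the correlation estimated. Per time point, p-values were adjusted over the 186 tests. Enrichment for rhythmic genes was tested by Fisher's exact test among all genes tested, adjusted over 62 tests. Some genes are not reported here.

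The gene lists, the rules for naming genes and the alternatives were fixed before the data were examined, apart from those given as chosen later. For the diet average the genes named were the 15 largest rises and 15 largest falls among genes past the threshold. At each time point they were the 3 largest rises and 3 largest falls. Genes were also named for the 10 smallest adjusted p of the diet by time test and of the rhythm difference, and the 12 largest amplitudes in each diet. All measured clock genes, and up to 4 members of each list described, were included. Predicted genes were passed over.

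The alternatives were the mean of a gene's probe sets, each probe set on its own, leaving out dim genes, trended and robust eBayes, array weights, array medians of all probe sets subtracted, the first residual component as a covariate and a replicate block. Others were leaving out each array, leaving out ZT8, leaving out each time point for the diet average, an additive model, fits on part of the arrays, the 5-coefficient test in place of the cosine, ranks, and other gene choices and list tests. Chosen after seeing the data were leaving out ZT12 for the other results, leaving out ZT8 and ZT12 together, the counts of lists without ZT8, time point of a diet as a random block, medians of the tested genes subtracted, and the log2 ratio of the 3-prime to the 5-prime actin control probe set as a covariate.

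The scripts were tested on simulated data for 17097 genes, with 100 genes changed by each size. For the diet average, 69% of genes changed by 0.2 and 100% of those changed by 0.5 on the log2 scale were recovered. At ZT12 the shares were 74% for 0.5 and 97% for 1. For diet by time they were 62% for 0.5 and 87% for 1. A cosine of amplitude 0.3 was recovered for 90% of genes in the control diet and 92% in the high fat diet, and a rhythm difference of 0.3 for 61%. False calls made up 2.29% to 6.92% of all calls. For the high fat rhythm (3.72%) and the rhythm difference (2.29%), genes simulated with only a ZT12 diet change did not count as false. Cosine calls that come from a change at ZT12 alone are therefore not covered by these shares. The simulations had no shared effect of collection day.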

Results

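Expression was measured in epidermal stem cells of mice kept on a control or a high fat diet and collected around the day. The control diet had 4, 3, 2, 3, 4 and 4 arrays at ZT0, ZT4, ZT8, ZT12, ZT16 and ZT20, and the high fat diet had 3, 4, 2, 4, 4 and 4. ZT is zeitgeber time, counted from lights on. The design allows 3 comparisons, which are the diets with each other, the time points within a diet, and the course over the day between the diets. The first principal component held 22.3% of the variance and the second 16.5%. On the second component the 2 control arrays of ZT8 stood apart at a mean of -37.9 ± 6.77 (SD, n = 2), and the high fat arrays of ZT12 lay at 20.4 ± 5.57 (SD, n = 4). The 2 high fat arrays of ZT8 differed widely on the first component (SD 17.4). These groups are therefore named beside each count they carry.

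The circadian clock genes cycled in both diets. Arntl, which encodes the activator BMAL1, peaked at ZT23.1 ± 0.717 (SE) in the control diet, with an amplitude of 1.01 ± 0.19 (SE, log2), and at ZT23.5 ± 0.432 with an amplitude of 1.60 ± 0.18 in the high fat diet. Its other probe set had amplitudes of 0.53 and 0.59. The repressor gene Per2 peaked at ZT14.1 in the control diet and ZT15.1 in the high fat diet, with amplitudes of 1.04 ± 0.09 and 0.89 ± 0.09 (2.33 and 1.93 in its other probe set). The output genes Dbp and Tef peaked at ZT11.1 and ZT12.5 in the control diet and at ZT11.2 and ZT12.4 in the high fat diet. Of 17 measured clock genes, 12 were rhythmic in the control diet and 14 in the high fat diet (14 and 14 adjusted over the list alone), an enrichment with adjusted p of 5.02e-10 and 4.51e-10 by Fisher's exact test. Arntl, Npas2, Per1, Per2, Per3, Cry1, Cry2, Nr1d2, Dbp, Tef, Hlf and Ciart passed in both diets. Nfil3 (adjusted p = 0.236 control, 0.00568 high fat) and Rora (0.187 and 0.0181) passed in the high fat diet, but the difference between diets did not pass for either (adjusted p = 0.429 and 0.447, limma). Clock, Bhlhe40 and Bhlhe41 passed in neither. Npas2 was the clock gene whose cosine differed between diets (adjusted p = 0.0354), with amplitudes of 0.46 ± 0.04 and 0.31 ± 0.04 (1.40 and 1.34 in its other probe set) and peaks at ZT23.6 and ZT21.9. With time point of a diet as a random block, 8 clock genes passed in the control diet and 10 in the high fat diet, and the Npas2 difference did not pass (adjusted p = 0.977).

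**Figure D1:**
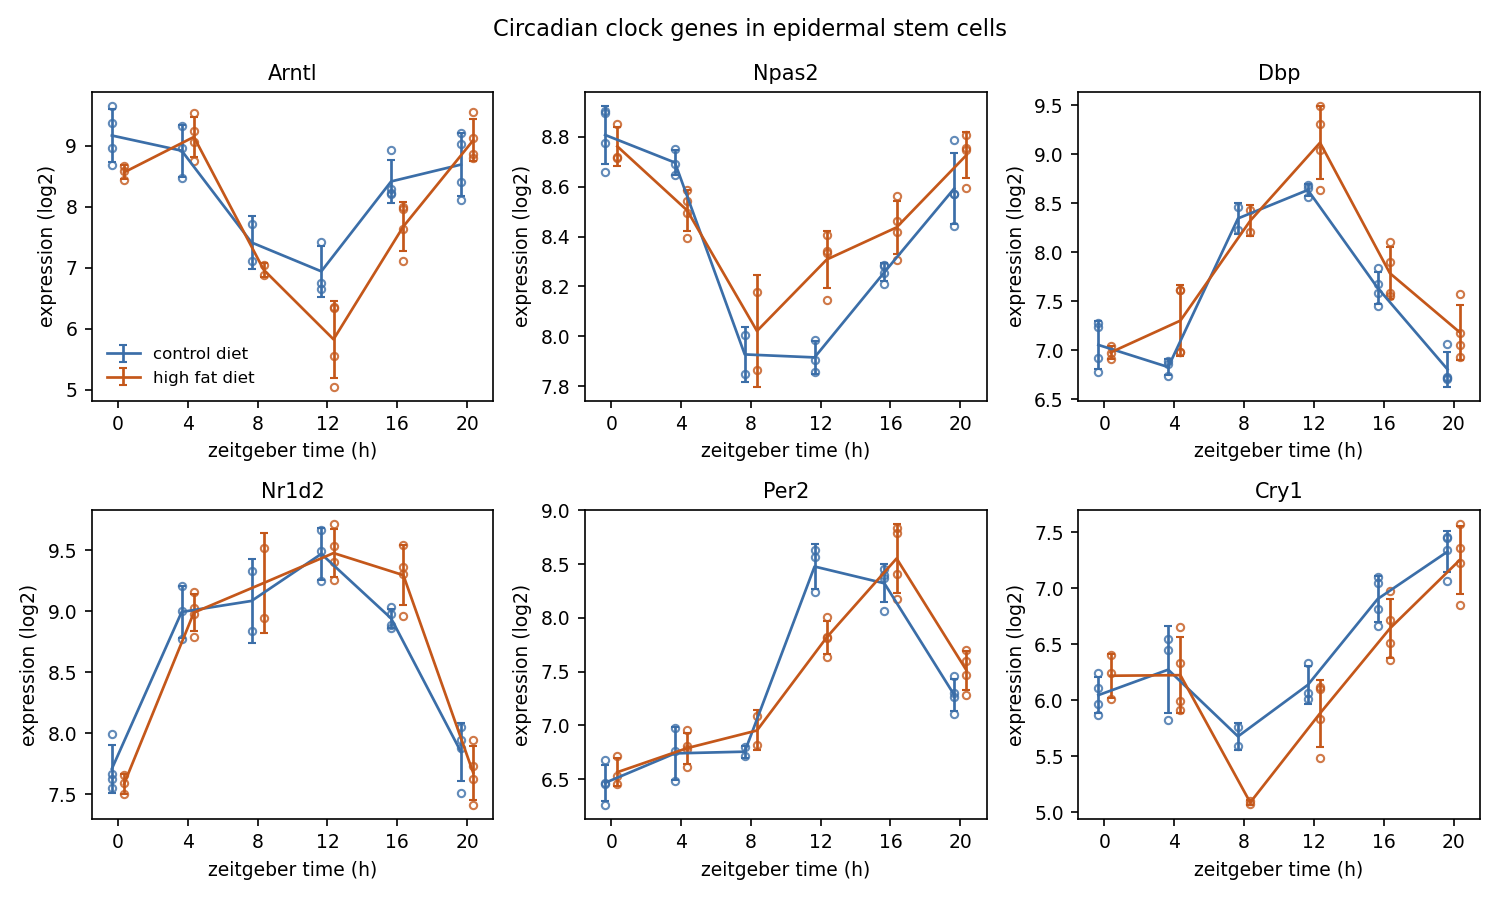
Expression (log2) of 6 clock genes against zeitgeber time (h), with open circles for arrays and lines with bars for the mean and SD of each diet and time point. At ZT12 Arntl lay at 5.83 ± 0.637 in the high fat diet and 6.94 ± 0.424 in the control diet.

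Genes of the cell division cycle also cycled in both diets. S phase genes were highest from ZT12 to ZT20 and mitosis genes from ZT20 to ZT0. Of 18 S phase genes, 16 were rhythmic in the control diet and 14 in the high fat diet (17 and 16 adjusted over the list alone), with enrichment at adjusted p of 9.52e-16 and 1.09e-09. The replication licensing gene Cdc6 peaked at ZT14.8 and ZT14.0, and Rrm2, a subunit of ribonucleotide reductase, at ZT18.6 and ZT18.3, in the control and high fat diets. Of 16 mitosis genes, 15 and 13 were rhythmic (16 and 15 adjusted over the list alone), with adjusted p of 9.52e-16 and 1.67e-09. The kinase gene Aurkb had amplitudes of 1.18 ± 0.16 and 1.19 ± 0.16 and peaked at ZT22.3 and ZT21.7. The topoisomerase gene Top2a peaked at ZT21.3 and ZT21.6, and the proliferation marker Mki67 at ZT22.2 and ZT21.9. Mcm2, a helicase subunit, was the S phase gene whose cosine differed between diets (adjusted p = 0.0354), with peaks at ZT16.4 and ZT13.2. No mitosis gene differed. With the random block, 8 and 2 S phase genes and 11 and 6 mitosis genes passed in the control and high fat diets. The Mcm2 difference did not pass with it (limma, adjusted p = 0.858).

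**Figure D2:**
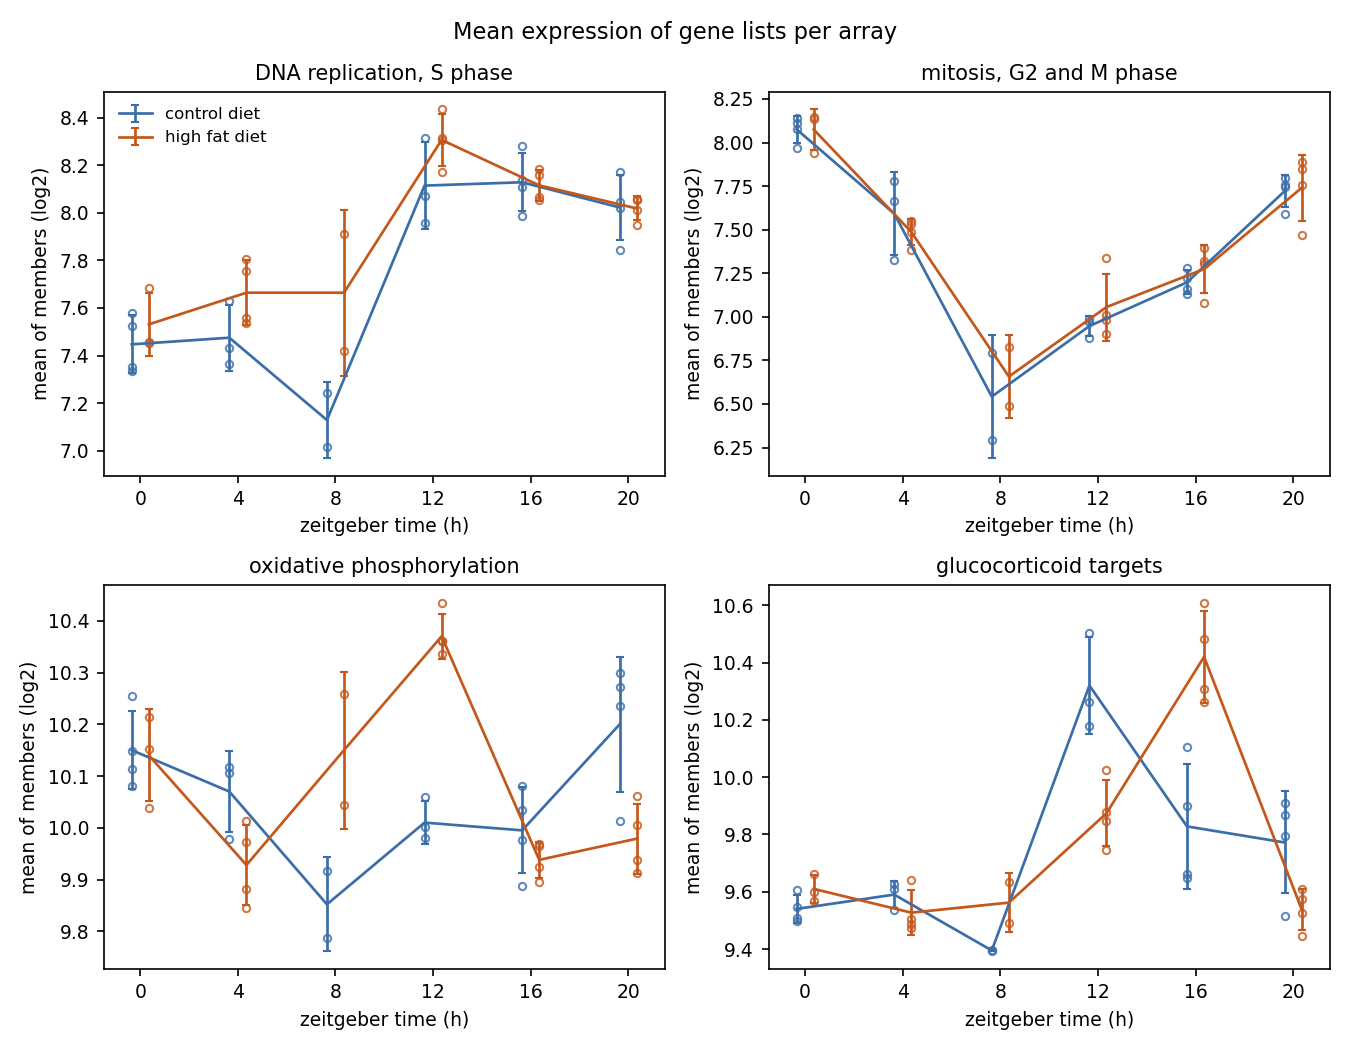
Mean expression (log2) of the members of 4 gene lists against zeitgeber time (h), with open circles for arrays and lines with bars for the mean and SD of each diet and time point. Glucocorticoid targets lay at 10.3 ± 0.168 at ZT12 in the control diet and at 10.4 ± 0.160 at ZT16 in the high fat diet.

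Over all genes, a 24 h cosine passed for 1138 genes in the control diet and 1908 in the high fat diet (3635 and 4717 at an unadjusted p under 0.05). Efemp1, which encodes a matrix protein, had the largest amplitude in the control diet among genes named by rule (1.35 ± 0.20). The cytochrome P450 gene Cyp1b1 followed, by the probe set used (1.29 ± 0.24). In the high fat diet Arntl, by the probe set used, was followed by Ptgs2 (1.24 ± 0.32) and Aurkb. Passing in both diets were 403 genes, where 127 would be shared by independent lists, and 249 of these peaked within 2 h of each other. The most frequent peak windows were centred on ZT20 in the control diet (356 genes) and on ZT12 in the high fat diet (620 genes). Many more genes differed between time points in any shape, 7499 and 7090 by the 5-coefficient test. Time point and collection day coincide here, and with time point of a diet as a random block 137 and 66 genes remained, 33 of them in both diets, and all 137 and 66 had also passed without the block. On ranks the cosine passed for 0 genes in the control diet and 572 in the high fat diet. The control count was 514 without ZT8, 637 without control ZT8 replicate 1 and 558 without control ZT8 replicate 2. The high fat count was 786 without ZT12, and the control count was 2007.

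Further lists were enriched for rhythmic genes in part of the comparisons. Cholesterol synthesis genes passed for 5 of 16 in the control diet and 6 in the high fat diet (adjusted p = 0.0158 and 0.0272), with Mvk at ZT5.96 and ZT7.10 and Fdft1 at ZT5.42 and ZT4.59. Fatty acid oxidation genes passed for 5 and 8 of 21 (0.0419 and 0.00710), among them Cpt1a, the carnitine transferase of mitochondrial import, at ZT4.64 and ZT9.26. Glycolysis genes passed for 5 and 2 of 12 (0.00476 and 0.740) and unfolded protein response genes for 5 and 4 of 13 (0.00657 and 0.158). Leukocyte and Langerhans cell markers passed for 6 and 0 of 13 (0.000869 and 1), with the cosines of the antigen presentation gene H2-Aa and of Cd52 differing between diets (adjusted p = 0.00890 and 0.0212) and that of H2-Ab1 not passing (0.0768). p53 and DNA repair genes passed for 0 and 7 of 14 (1 and 0.00278), and none of these 14, the 12 glycolysis, the 13 unfolded protein response or the 8 glucocorticoid target genes had a cosine that differed between diets (limma). Bulge genes passed for 2 and 5 of 12 (0.448 and 0.0308), glucocorticoid targets for 2 and 4 of 8 (0.245 and 0.0309) and oxidative phosphorylation genes for 2 and 7 of 24 (0.858 and 0.0485). The other 19 lists were not enriched in either diet. Of 62 enrichments 17 passed, and 6 with the random block, with which each list named in this paragraph kept 0 or 1 rhythmic member per diet. The number was 10 without high fat ZT12 replicate 2, and 11 without control ZT8 replicate 2, high fat ZT12 replicate 1 or high fat ZT12 replicate 4.

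Averaged over the time points, the high fat diet changed 1297 genes, 944 upward and 353 downward (4155 at an unadjusted p under 0.05), mostly by small amounts. The median absolute change of these genes was 0.155 on the log2 scale, 6 changed by at least 1.5-fold and 0 by at least 2-fold. The transcription factor gene Maf rose by 0.47 ± 0.05 (SE, log2, adjusted p = 6.90e-06), and Postn, which encodes the matrix protein periostin, by 0.59 ± 0.09 (0.000271, higher at 6 of 6 time points). The cystatin gene Stfa3 rose by 0.78 ± 0.15 (0.00299), the collagen gene Col6a1 by 0.49 ± 0.11, the integrin ligand gene Npnt by 0.51 ± 0.11, the ligand gene Wnt5a by 0.46 ± 0.09, the thrombin receptor gene F2r by 0.54 ± 0.09 and the transglutaminase gene Tgm3 by 0.46 ± 0.08. The stress genes Gadd45a and Phlda1 rose by 0.73 ± 0.20 and 0.66 ± 0.16, Ccdc3 by 0.47 ± 0.08, Antxr1 by 0.46 ± 0.11 and Guca2a by 0.50 ± 0.09. Among falls, the channel family gene Ano9 fell by 0.58 ± 0.09 (adjusted p = 0.000348, lower at 6 of 6 time points), Ttc39c by 0.49 ± 0.10 and the epidermal lipoxygenase gene Alox12e by 0.45 ± 0.09. The ribonuclease gene Ear3 fell by 0.90 ± 0.16, Cyp1b1 by 0.68 ± 0.12, the surface glycoprotein gene Cd200 by 0.55 ± 0.14 and the retinoic acid binding gene Crabp2 by 0.42 ± 0.13. Ear3, Cyp1b1 and F2r were also among the largest changes at ZT8, where the 2 control arrays stood apart. Their averages therefore rest in part on that time point. At least 1 other probe set of Cyp1b1, Clca1, Slc1a1, Rassf3 and Ccdc93 had a small positive difference, and with the mean of a gene's probe sets Slc1a1, Rassf3, Lin7b and Ccdc93 did not pass. The count rested on ZT12, with 198 genes without ZT12, 875 without ZT8, 246 without both and 611 without control ZT8 replicate 2. Of the 30 genes named by rule, Postn, Maf, Ccdc3 and Tgm3 passed under every alternative run. The share of rises depended on the centring, being 72.8% as deposited, 76.5% with array medians of all probe sets subtracted and 40.9% with medians of the tested genes subtracted.

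S phase genes were the list that rose on the diet average. All 18 had a positive difference and 4 passed, namely Cdt1 (0.44 ± 0.09, adjusted p = 0.00312), Mcm2 (0.39 ± 0.09), Uhrf1 (0.30 ± 0.08) and Mcm5 (0.34 ± 0.11), with 5 adjusted over the list alone. Camera gave an adjusted p of 0.000859 with the preset correlation, and an adjusted p of 0.713 with an estimated correlation, with which no list passed. The median difference of the list was largest at ZT8 (0.44) and second at ZT12 (0.18), and 0 lists passed by camera without the ZT8 arrays, a count chosen after seeing the data. The number of lists was 6 without high fat ZT8 replicate 2, 4 without control ZT0 replicate 2 or high fat ZT4 replicate 3, and 2 without any of control ZT0 replicate 1, control ZT4 replicate 1, control ZT8 replicate 1, control ZT16 replicate 4, control ZT20 replicate 1, control ZT20 replicate 4, high fat ZT0 replicate 1, high fat ZT0 replicate 2, high fat ZT4 replicate 1, high fat ZT8 replicate 1 and high fat ZT16 replicate 2, each left out in turn.

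The diets differed in 3086 genes at ZT12 and 1426 at ZT8, and in 146, 66, 212 and 120 at ZT0, ZT4, ZT16 and ZT20. The genes of ZT8 and ZT12 overlapped, with 523 in common where independent lists would share 257, and 490 of them moved in the same direction. The correlation of the differences at ZT8 and ZT12 was 0.351 across genes, which are not independent replicates. At the time points alone, without the spread of the other groups, the counts were 117, 0, 0, 1829, 67 and 0 from ZT0 to ZT20. As deposited, 52.7%, 47.0%, 46.7% and 44.2% of the changed genes were higher at ZT0, ZT4, ZT16 and ZT20. With array medians of all probe sets subtracted the shares were 59.6%, 29.0%, 54.0% and 32.6%, and with medians of the tested genes 41.3%, 40.8%, 44.3% and 33.1%. The diet effect differed between time points for 3251 genes by the F test (6211 at an unadjusted p under 0.05), 1485 without ZT12, 2575 without ZT8 and 294 without both.

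**Figure D3:**
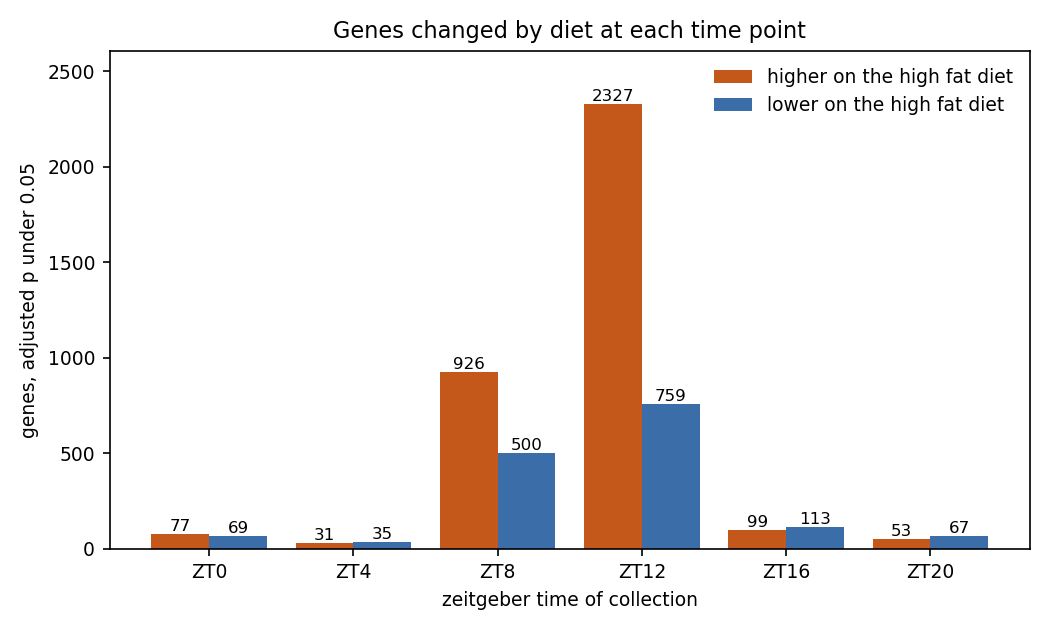
Genes past an adjusted p of 0.05 (bars from 0) at each zeitgeber time of collection, split into those higher and those lower on the high fat diet. ZT12 had 2327 higher and 759 lower, and ZT4 had 31 and 35.

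At ZT12 oxidative phosphorylation and fatty acid oxidation genes were higher on the high fat diet and immediate early genes were lower. Glycolysis genes did not shift, with 1 of 12 passing (median 0.04, camera unadjusted p = 0.645). Of 24 oxidative phosphorylation genes, 16 rose and 0 fell (18 and 0 adjusted over the list alone), with the respiratory chain genes Ndufa4 at 0.90 ± 0.15 (SE, adjusted p = 0.000149), Ndufa2 at 0.59 ± 0.11, Ndufa1 at 0.48 ± 0.08 and Cox4i1 at 0.36 ± 0.06. Camera gave an adjusted p of 1.09e-07, and an adjusted p of 0.494 with an estimated correlation. Of 21 fatty acid oxidation genes 12 rose and 0 fell (13 and 0 adjusted over the list alone), with the beta-oxidation genes Hadhb at 0.45 ± 0.09, Acaa2 at 0.45 ± 0.10, Acadl at 0.37 ± 0.08 and Acadvl at 0.31 ± 0.07 (camera 0.00315, and adjusted p = 0.482 with an estimated correlation). Of 15 immediate early genes 10 fell and 0 rose (11 and 1 adjusted over the list alone), with Egr2 at -0.52 ± 0.12, Klf6 at -0.37 ± 0.08, Fosb at -0.28 ± 0.05 and Egr1 at -0.23 ± 0.06 (camera 4.36e-07, and adjusted p = 0.536 with an estimated correlation). Of 17 clock genes 5 fell and 1 rose (5 and 2 adjusted over the list alone), with Arntl at -1.11 ± 0.31 (-0.08 in its other probe set), Nfil3 at -0.75 ± 0.20, Per2 at -0.66 ± 0.14 and Npas2 at 0.39 ± 0.08 (camera 0.00505, and adjusted p = 0.482 with an estimated correlation). Of 8 glucocorticoid targets 2 fell, the transcription factor gene Zbtb16 by 1.36 ± 0.21 and the chaperone gene Fkbp5 by 1.18 ± 0.30 (camera 0.00513, and adjusted p = 0.369 with an estimated correlation). Of 8 melanocyte markers 2 fell, Pmel by 0.89 ± 0.18 and Sox10 by 0.20 ± 0.06, and the list did not shift (median -0.06, camera adjusted p = 0.0519), and of 13 leukocyte markers 6 rose and 1 fell (camera 0.355). The largest changes named by rule were S100a4 at 1.41 ± 0.17, Rpl14 at 1.40 ± 0.18, Zc3h14 at 1.39 ± 0.33, Cd55b at -1.69 ± 0.24, Nlrc3 at -1.60 ± 0.26 and Megf11 at -1.58 ± 0.26. The count was 1700 without control ZT12 replicate 2 and 1938 without control ZT12 replicate 1, and the share of rises was 75.4% as deposited and 51.0% with medians of the tested genes subtracted.

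At ZT8, with 2 arrays per diet, S phase, oxidative phosphorylation and glycolysis genes were higher on the high fat diet and cholesterol synthesis genes lower. Of 18 S phase genes 5 rose (9 adjusted over the list alone), with Mcm2 at 1.49 ± 0.27 and Mcm5 at 1.23 ± 0.33, with camera at 3.14e-05 and an adjusted p of 0.536 with an estimated correlation. Of 24 oxidative phosphorylation genes 6 rose (11 adjusted over the list alone), with Ndufa1 at 0.70 ± 0.11 and Cycs at 0.52 ± 0.09, with camera at 3.28e-06 and an adjusted p of 0.536 with an estimated correlation. Of 12 glycolysis genes 3 rose (7 adjusted over the list alone), with Gapdh at 0.33 ± 0.06 and Tpi1 at 0.61 ± 0.13 (camera 0.00233, and adjusted p = 0.536 with an estimated correlation). Of 16 cholesterol synthesis genes 1 fell, the sterol carrier gene Stard4 at -1.30 ± 0.38 (3 adjusted over the list alone, camera 0.000226, and adjusted p = 0.536 with an estimated correlation). The control arrays of ZT8 stood apart from the mean of the 12 groups in many lists at once, with -0.67 in S phase, -0.21 in oxidative phosphorylation, -0.33 in glycolysis and 0.69 in cholesterol synthesis genes, and also -0.67 in basal, 0.49 in suprabasal, -0.44 in fibroblast and -0.31 in leukocyte genes. The high fat arrays lay at -0.14, 0.09, -0.09 and 0.21, and at -0.39, 0.29, -0.17 and -0.07. Hair matrix genes shifted down with 2 of 11 falling, the hair keratins Krt25 at -0.86 ± 0.14 and Krt71 at -0.62 ± 0.18 (camera 0.00539, and adjusted p = 0.369 with an estimated correlation). The basal keratin Krt14 rose by 0.37 ± 0.10, and the suprabasal genes Dsg1a, Sbsn and Calm4 fell by 0.63 ± 0.15, 0.55 ± 0.14 and 0.64 ± 0.20. Neither list shifted (1 of 11 basal genes, camera adjusted p = 0.0633, and 3 of 16 suprabasal genes, 0.0519), and the suprabasal mean was 8.83 and 9.74 in the high fat arrays and 9.59 and 9.39 in the control arrays. Of 11 fibroblast markers 2 rose and 1 fell (camera 0.521), and of 13 leukocyte markers 2 rose (0.355). The largest changes were Ear3 at -3.51 ± 0.50, Cyp1b1 at -2.69 ± 0.38, Dclk1 at -2.36 ± 0.61, F2r at 2.32 ± 0.28, Fndc3b at 1.94 ± 0.32 and Efemp1 at 1.78 ± 0.40. The count was 318 without control ZT8 replicate 2 and 676 without high fat ZT8 replicate 1, fits in which the lone array is assumed to vary like the other groups. The share of rises was 64.9% as deposited and 47.6% with medians of the tested genes subtracted.

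At ZT16 glucocorticoid targets were higher on the high fat diet. All 8 had a positive difference, 1 passed over all genes and 8 adjusted over the list alone, with camera at 4.36e-07. This was the list shift that also passed with an estimated correlation (adjusted p = 0.0346), the only case among the 186 tests. The glucocorticoid-induced leucine zipper gene Tsc22d3 rose by 1.46 ± 0.20 (SE, adjusted p = 0.000130), while Fkbp5 at 0.86 ± 0.28 (adjusted p = 0.103) and Sgk1 at 0.37 ± 0.11 (0.0727) did not pass over all genes. Tsc22d3 did not differ detectably at ZT12 (0.06 ± 0.21, adjusted p = 0.874) and fell by 0.86 ± 0.20 at ZT20. Unfolded protein response genes shifted down, with 3 of 13 falling and 1 rising (6 and 1 adjusted over the list alone). The chaperone genes Creld2, Hsp90b1 and Calr fell by 0.84 ± 0.10, 0.39 ± 0.07 and 0.37 ± 0.10, and Herpud1 rose by 0.58 ± 0.09 (camera 0.00112, and adjusted p = 0.369 with an estimated correlation). Fatty acid oxidation and PPAR target genes shifted up, with Angptl4 at 0.58 ± 0.13, Acadm at 0.43 ± 0.10 and, against the list, the lipid droplet gene Plin2 at -0.41 ± 0.10 (camera 0.00271, and adjusted p = 0.482 with an estimated correlation). Other large changes were Tent5b at 1.38 ± 0.28, Crispld2 at 1.23 ± 0.29, Zkscan3 at -0.96 ± 0.18, Ptpn6 at -0.92 ± 0.16 and Limk1 at -0.90 ± 0.19. The count was 82, 84, 119 and 350 without control ZT16 replicates 1, 2, 3 and 4, and 113 and 120 without high fat ZT16 replicates 1 and 4.

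At ZT0 single genes rose on the high fat diet, and at most 2 members of any list passed. The chemokine receptor-like gene Ccrl2 rose by 1.52 ± 0.20 (SE, adjusted p = 0.000141), the cyclooxygenase gene Ptgs2 by 1.90 ± 0.46, the sterol hydroxylase gene Ch25h by 1.62 ± 0.37 and the NF-kB feedback gene Tnfaip3 by 1.18 ± 0.18. Of 15 immediate early genes 1 rose, Egr2 by 0.55 ± 0.12 (8 adjusted over the list alone), with camera at 9.58e-06 and an adjusted p of 0.536 with an estimated correlation. NF-kB targets shifted up (2 of 14, camera 0.0171, and adjusted p = 0.494 with an estimated correlation). Leukocyte and Langerhans cell markers shifted down, with H2-Aa falling by 0.49 ± 0.11 (camera 0.00300, and adjusted p = 0.369 with an estimated correlation). Lrrc49, Ankrd52 and Cwf19l2 fell by 1.44 ± 0.29, 1.22 ± 0.24 and 1.16 ± 0.26. The actin 3-prime to 5-prime difference was -0.698 ± 0.0731 (SD, n = 4) in the control arrays of ZT0 and -0.604 ± 0.0676 (SD, n = 3) in the high fat arrays, and with it as a covariate 15 genes passed. The count was 44 without control ZT0 replicate 3, 31 without high fat ZT0 replicate 2 and 20 without high fat ZT0 replicate 3.

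At ZT4 and ZT20 the diets differed in 66 and 120 genes. Among them at ZT4 the matricellular gene Ccn4 rose by 1.10 ± 0.24, Exoc6 by 0.70 ± 0.12 and Dalrd3 by 0.61 ± 0.14, while Rab11fip5, Lce1b and the pseudogene Speer8-ps1 fell by 0.80 ± 0.14, 0.69 ± 0.15 and 0.92 ± 0.20. No member passed in the 3 lists that shifted there, which were S phase upward (median 0.15, camera 0.00885), and oxidative phosphorylation (-0.12, camera 0.000229) and fatty acid oxidation (-0.12, camera 0.0400) downward. Their adjusted p values with an estimated correlation were 0.692, 0.691 and 0.555. At ZT20 oxidative phosphorylation genes shifted down, the opposite of ZT8 and ZT12, with 2 of 24 falling, Uqcrb by 0.39 ± 0.08 and Cycs by 0.28 ± 0.06 (9 adjusted over the list alone, camera 2.08e-10, and adjusted p = 0.369 with an estimated correlation). Apbb3, the integrin gene Itga5 and the growth factor gene Tgfb1 rose by 1.02 ± 0.16, 0.98 ± 0.23 and 0.80 ± 0.20, and Dcakd and Npat fell by 0.99 ± 0.24 and 0.87 ± 0.20. The ZT4 count was 9, 7 and 113 without control ZT4 replicates 1, 2 and 3, 0, 12, 29 and 11 without high fat ZT4 replicates 1, 2, 3 and 4, and 34 without control ZT12 replicate 3. The ZT20 count was 26, 302, 37 and 34 without control ZT20 replicates 1, 2, 3 and 4, 20, 40 and 79 without high fat ZT20 replicates 2, 3 and 4, and 184 without either high fat ZT8 array.

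Many genes had a diet effect that changed over the day. The smallest adjusted p values of the diet by time test belonged to Txndc17 (1.46e-07), the sterol carrier gene Scp2 (4.35e-07), and Btf3, Gna15, Kmt2c and Tomm7 (9.02e-06 each), followed by Eloc, Rpl36a, Rpl36al and Rps21 (1.03e-05 each). Scp2 was 0.79 higher on the high fat diet at ZT8 and 0.62 higher at ZT12, with -0.31 at ZT0 and -0.25 at ZT20. Kmt2c ran the other way, with -0.34 at ZT8, -0.48 at ZT12 and 0.30 at ZT20. Of the fixed lists, the 7 with the largest shares of members whose effect differed between time points were oxidative phosphorylation (18 of 24), the unfolded protein response (9 of 13), heat shock (6 of 9), glucocorticoid targets (5 of 8), immediate early genes (9 of 15), fatty acid oxidation (11 of 21) and the clock (8 of 17), against 3251 of 17097 over all genes. Enrichment was not tested for these. The cosine itself differed between diets for 612 genes (2991 at an unadjusted p under 0.05). Of these Scp2 peaked at ZT21.6 in the control diet and ZT10.5 in the high fat diet, the elongin gene Eloc at ZT20.3 and ZT11.3 and the ribosomal protein gene Rpl14 at ZT21.4 and ZT10.4, and 11 oxidative phosphorylation genes were among them. Of the 735 genes rhythmic in the control diet and not in the high fat diet 101 had a difference that passed, and of the 1505 with the reverse 351. The count was 10 without ZT12, 467 without ZT8, 6 without both, 1 with time point of a diet as a random block, 385 without control ZT8 replicate 2, and 356, 364 and 386 without high fat ZT12 replicates 1, 3 and 4.

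No general difference between the diets in amplitude or peak time was detected over the 2137 genes with a common rhythm. These genes were chosen for a cosine shared by both diets, which favours genes with like peaks. The test therefore does not cover genes whose peaks lay far apart. The median log2 ratio of amplitudes, high fat over control, was -0.06 (p = 0.870 over 100 permutations of diet within time points, two-sided, where the SD of permuted values was 0.175). The circular mean shift of the peak was -0.134 h (permutation p = 0.560, SD 0.266 h), and 1311 genes had peaks within 2 h. The ratio was 0.11 without control ZT8 replicate 2 and 0.19 without the ZT8 arrays, and the shift was 0.140 h without control ZT4 replicate 3, 0.186 h without the ZT8 arrays and 0.886 h over the clock list alone.

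The remaining lists did not shift by camera in any diet comparison. On the diet average, of 11 basal keratinocyte genes 1 rose, of 16 suprabasal genes 1 rose, of 8 stress keratins and alarmins 2 rose, and of 12 bulge genes 2 rose and 1 fell. Of 16 antioxidant genes 2 rose, of 15 fatty acid synthesis genes 1 fell, of 9 heat shock genes 1 rose and 1 fell, of 10 BMP and TGF-beta targets 1 rose, of 14 p53 and DNA repair genes 1 rose, and of 10 interferon genes, 9 Wnt genes and 16 mitosis genes 0 passed. Few markers of other cell types passed on the diet average, though such counts do not exclude a small shift shared by the markers of a cell type. Of 11 fibroblast markers 1 rose, of 8 endothelial markers 1 rose and 1 fell, of 8 skeletal muscle markers 1 rose and of 11 hair matrix markers 1 rose, while 0 of 6 adipocyte, 13 leukocyte, 8 melanocyte, 3 erythroid and 5 sebocyte markers passed (limma, adjusted over all genes).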

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

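The tests of the ribosomal protein genes, which belong to the second paragraph, were chosen only after the result was seen. Of 70 tests for a single array standing apart from its group, 5 passed the limit, and chance flags about 1 in 20 groups. These were control ZT16 replicate 4 on the second principal component (-1.06) and in Arntl (8.94, log2), and high fat ZT20 replicate 1 on the second component (5.65). The others were control ZT20 replicate 2 in Dbp (7.07, log2) and control ZT0 replicate 3 in its mean correlation with its group (0.9935). That correlation was the highest of its group, so it does not mark a poor array.

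A test of the difference itself found 3251 genes whose diet effect differed between time points and 612 whose cosine differed between diets. Among 100 drawn splits of the diet labels within time points, the real one included, 1 gave as many genes in each case, the real one, which argues against chance. The highest of the others gave 1928 and 1 genes. The lowest adjusted p values of the diet by time test were 1.46e-07 for Txndc17, 4.35e-07 for Scp2, 9.02e-06 for Btf3, Gna15, Kmt2c and Tomm7, and 1.03e-05 for Eloc, Rpl36a, Rpl36al and Rps21. Those of the rhythm difference were 0.000115 for Scp2, 0.000199 for Eloc, Rpl19, Rpl26, Rps26 and Ywhaq, 0.000437 for Rps21, 0.000650 for Mrpl20 and Rpl23a, and 0.000677 for Rpl14. Without ZT12 the counts were 1485 and 10, without ZT8 2575 and 467, and without both 294 and 6.

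Signal also lay in the 15588 probe sets for which no gene name was used here. Of these, 1576 changed on the diet average and 3237 at ZT12, and 408 and 1023 were rhythmic in the control and high fat diets. They hold 6346 probe sets brighter than the median of all.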

How the results depend on the processing

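Chosen only after the results were seen were leaving out ZT12 for results other than the diet average, leaving out ZT8 and ZT12 together, the list counts without ZT8, time point of a diet as a random block, medians of the tested genes subtracted, and the actin covariate. The cause of the changes below was not tested, except where the construction shows it, as for each probe set on its own, which tests more items than genes.

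With every probe set on its own the counts were 2121 for the diet average, 259, 2221, 4994, 437 and 202 at ZT0, ZT8, ZT12, ZT16 and ZT20, 5117 for diet by time, and 1734 and 2935 rhythmic in the control and high fat diets. With dim genes left out they were 7 at ZT4, 2 lists shifted on the diet average and 10 enrichments for rhythmic genes. Array weights gave 438, 379, 558 and 360 at ZT0, ZT8, ZT16 and ZT20. The first residual component as a covariate gave 323, 114, 478 and 332 at ZT0, ZT4, ZT16 and ZT20, 1833 and 3060 rhythmic genes, 1264 rhythm differences and 5 lists shifted. The actin covariate gave 15 at ZT0.

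Replicate numbers did not pair the arrays. Of 19 pairs of a control and a high fat array with the same number, 2 had a residual correlation over 0.1 and 2 correlated best with their own number, with correlations from -0.272 to 0.248. The replicate block therefore served only as an alternative and gave 720 genes for the diet average, 49, 0, 68 and 0 at ZT0, ZT4, ZT16 and ZT20, and 1536 for diet by time.

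Without ZT8 the counts were 210 at ZT20, 514 rhythmic in the control diet and 0 lists shifted, with an amplitude ratio of 0.19 and a phase shift of 0.186 h. Without ZT12 they were 198 for the diet average, 1485 for diet by time, 2007 and 786 rhythmic genes, 10 rhythm differences and 7 lists shifted. Without ZT8 and ZT12 they were 246, 294, 1266 rhythmic in the high fat diet, 6 rhythm differences, 5 lists shifted and 10 enrichments. In this last setting the diet average changed sign for Cox4i1 (-0.0417), Ndufa1 (-0.110) and Gpx1 (-0.0188). There the high fat peak also moved by more than 6 h for Ndufa2, Txnrd1, Mdm2, Hspe1, Pmel and Rora (amplitudes 0.0864, 0.174, 0.0735, 0.113, 0.298 and 0.204).

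The additive model gave 418 genes for the diet average. Fits to a time point alone gave 0, 0, 1829, 67 and 0 at ZT4, ZT8, ZT12, ZT16 and ZT20, and a fit to the control diet alone gave 746 rhythmic genes. The 5-coefficient test gave 7499, 7090 and 3251 genes for control, high fat and difference, and 26 enrichments. Ranks gave 0, 572 and 175, and time point as a random block 137, 66 and 1, with 6 enrichments. The phase shift was -0.417 h over genes rhythmic in each diet and 0.886 h over the clock list. Lists shifted numbered 0 with an estimated correlation and 8 by fry.

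Leaving out each array in turn gave 611 to 1807 for the diet average, 20 to 168, 0 to 113, 318 to 1556, 1700 to 3216, 82 to 350 and 20 to 302 from ZT0 to ZT20, and 2510 to 3446 for diet by time. Rhythmic genes ranged from 558 to 1280 in the control diet and 1325 to 2127 in the high fat diet, and rhythm differences from 356 to 788. The amplitude ratio ran from -0.16 to 0.11, the phase shift from -0.289 to 0.140 h, lists shifted from 1 to 6 and enrichments from 10 to 18. Of 29794 repeats of results for named genes, 27239 kept direction and side of the threshold, 2502 fell short of it, 44 newly passed and 9 reversed. Subtracting array medians moved no total of changed or rhythmic genes by over 1.5 times. With medians of the tested genes, rises and falls did move, from 944 and 353 to 470 and 680 on the diet average and from 2327 and 759 to 1320 and 1270 at ZT12. Lists were not counted again under either.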

Other observations

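The test of ribosomal protein genes, the orders of time points for gene counts and for the clock list, the actin covariate, the regrouping of ZT12 and ZT16 arrays and the permutation over all lists were chosen only after the result was seen. Ribosomal protein genes moved with diet and time as a group. Of 56 not named by rank, 43 had a cosine that differed between diets, against 551 of 17022 other genes (odds ratio 98.6, Fisher exact p = 5.24e-52, with genes not independent of each other). None of the 56 passed with time point of a diet as a random block, where 1 gene passed in all (Scp2, adjusted p = 0.0219), or without ZT12, where 10 passed (limma). Their median difference by diet was 0.24 at ZT8 (54 of 56 positive) and 0.23 at ZT12 (53 of 56), and -0.11 at ZT20 (0 of 56). Oxidative phosphorylation genes ran the same way, with 0.31, 0.39 and -0.22. A shared change in growth or energy state is a hypothesis that was not tested. Measuring ribosomal protein transcripts at ZT8, ZT12 and ZT20 by another method in new mice would test the pattern, not its cause. A bias of the amplification toward short transcripts was not tested and remains open.

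Clock genes of the control curves placed high fat arrays earlier than control arrays by -2.15 h at ZT0 (exact p = 0.0571), -1.88 h at ZT12 (0.0286) and -1.05 h at ZT16 (0.0571), and later by 4.13 h at ZT4 (0.0286). At ZT8 and ZT20 the differences were 0.450 h (0.667) and -0.488 h (0.114). None passed over the 6 time points (lowest adjusted p = 0.0856), and 0.0286 is the smallest p that 3 against 4 arrays can give. On these curves the control arrays of ZT4 themselves lay at -4.58 ± 2.24 h (SD, n = 3) from their collection time. Those of ZT0 lay at 2.34 ± 0.760 h (SD, n = 4). The high fat arrays lay at 0.183 ± 1.97 h (SD, n = 3) at ZT0 and -0.45 ± 0.876 h (SD, n = 4) at ZT4. Both the 4.13 h and the -2.15 h therefore rest mainly on those control arrays. At ZT12 the high fat arrays lay at -2 ± 0.515 h (SD, n = 4) and the control arrays at -0.117 ± 0.0289 h (SD, n = 3). On the high fat curves the control arrays lay at 2.82 h (ZT0), -1.42 ± 0.104 h (ZT4, SD, n = 3), -0.375 h (ZT8), 1.25 h (ZT12), 1.00 h (ZT16) and 0.862 h (ZT20) from their collection times.

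Many more genes differed between time points than followed a cosine. Of the 60 circular orders of the time points, 31 gave as many cosine genes as the real one in the control diet (1138, highest 3528) and 21 in the high fat diet (1908, highest 4254). The gene counts are therefore not specific to the real order, as an effect of collection day could give, and day cannot be separated from time here. For the clock list 2 of 60 orders fitted as well, the real one (share of variance 0.739) and one with ZT0 and ZT4 exchanged (0.746). The exchanged order also gave more cosine genes, 3113 in the control diet and 4133 in the high fat diet. With it 14 and 15 clock genes passed, against 12 and 14 in the real order. For the cell cycle lists 1 of 60 orders fitted as well, the real one (0.622, next 0.549, exchanged 0.489). This argues for time of day in these lists, but the clock list does not settle the order of ZT0 and ZT4. Handling stress as read by immediate early genes did not account for most of the differences between control time points. The control group means of these genes ran only from 11.31 to 11.58 (log2), so a covariate made of them had little to remove. Handling stress that leaves these genes unchanged was not tested and stays open. With these genes as a covariate, 96.3% of the genes of the 5-coefficient test were still called in the control diet. In the high fat diet 5427 were called with it, the immediate early genes left out, against 7090 over all genes without it. For the cosine genes, 1 of 100 splits of the arrays over time points, the real one, gave as many in each diet. The highest others gave 70 and 614, which argues against a random grouping of the arrays. These splits break up the arrays of a time point, so any effect shared by a time point could give this result. They therefore do not tell a rhythm from an effect of collection day. The 5-coefficient counts were not split in this way.

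The diets differed in more genes at ZT12 than at other times. Of 35 splits of the 7 arrays 1, the real one, gave as many genes (3086, highest other 1858), and 9 of the others gave any genes. This argues against chance for a diet difference at ZT12 but does not exclude it, since 1 of 35 is the smallest share possible. The rank of ZT12 among the time points was not tested. RNA quality as read by the actin ratio is argued against as the whole cause, since 3270 genes passed with it as a covariate. A different circadian phase of the high fat mice stays open for genes outside the oxidative phosphorylation list. The shift of -1.88 h was neither as large as 2 h nor under 1 h. The mean of that list was 10.37 ± 0.0431 (SD, n = 4) in the high fat arrays of ZT12. Control group means ran from 9.852 at ZT8 to 10.2 ± 0.131 (SD, n = 4) at ZT20, with 10.01 at ZT12. An earlier time on the control course would lower this mean, so these values argue against phase alone for that list. A different collection day of the 2 diets, which the design text does not rule out, also stays open, as does diet itself.

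Glucocorticoid targets were highest at ZT12 in the control diet and at ZT16 in the high fat diet, a change of the diet effect by 1.03 (log2) with an exact p of 0.000408 over 2450 regroupings, the smallest they can give, which excludes nothing since the list and the times were picked for the pattern. Against the largest change of any of 31 lists and 15 pairs of time points, the permutation p was 0.001, the smallest that 1000 draws can give (t = 7.76, highest other 6.70), which argues against chance. With immediate early genes as a covariate the change was 0.93, which argues against handling stress as read by these genes as the whole cause. Their group means ran only from 11.31 to 11.64 (log2). Handling stress that leaves these genes unchanged was not tested and stays open. A different circadian phase at ZT16 stays open at -1.05 h, as does collection day. A later daily rise of corticosterone on the high fat diet is a hypothesis, which hormone measured over the day in both diets would test. A delay alone does not predict the values at ZT20. There the list lay at 9.538 ± 0.0721 (SD, n = 4) in the high fat diet and 9.772 ± 0.178 (SD, n = 4) in the control diet.

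For the remaining counts, 1 split, the real one, gave as many genes in each case, which argues against chance. Of 100 splits this held for the diet average (1297, highest other 581). Of 35 splits each it held at ZT0 (146, highest other 28), ZT4 (66 and 8), ZT16 (212 and 1) and ZT20 (120 and 4). ZT8, with 2 arrays per diet, was not tested in this way. At a single time point chance is not excluded, since 1 of 35 is the smallest share these splits can give. The shares were not adjusted over the time points. Fitted alone, ZT0, ZT4, ZT16 and ZT20 gave 117, 0, 67 and 0 genes.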
